A study of Mus musculus with 6 samples.

How the data were processed

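The series holds 6 arrays of E12.5 mouse spinal cord cells, sorted by flow cytometry into Hb9::GFP-on (motor neuron) and GFP-off (non-motor-neuron) fractions. There were 2 motor neuron arrays and 1 non-motor-neuron array for each genotype label (mir-17~92 knockout and wild type). RNA was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, all on 1 slide read in 1 scan; the knockout-labelled motor neuron arrays lay in slide row 1 and the other 4 in row 2. Descriptions give the first motor neuron replicate and the non-motor-neuron array of each genotype label a shared tag, whose meaning is not stated.

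Per the file headers, spots were quantified with Agilent Feature Extraction 10.5.1.1; the submitters' processing notes name version 9.1. The deposited scanner files give the processed signal of each spot as an intensity that is background-subtracted, detrended within the array and floored, with no scaling between arrays. They also give raw median signal and background intensity, and flags of other kinds, coded as present or absent, for spots above background, saturated or irregular. The authors' value table is in log2: it equals the log2 processed signal, averaged over a probe's spots, minus the 75th percentile of the array, within a tolerance of 0.01, with no centring of genes. No spot was saturated.

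The values used here were log2 processed signals averaged over the unflagged spots of each probe, minus the array's 75th percentile. Probes were named only through their RefSeq accession in a table of assembly GRCm38.p6; the file headers name mm9, so no coordinates are given. Of 55681 probes, 26300 matched a gene (19897 genes) and 29381 did not. A probe was kept if well above background on at least 2 of the 6 arrays and not flagged throughout an array, and the probe with the highest mean represented its gene, which left 14917 genes; 10135 were above background on all 6 arrays. Mnx1, the gene of the Hb9 reporter, had no matched probe.

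Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The genotype comparison in motor neurons and the interaction came from a model of 4 group means, with 2 residual degrees of freedom. These come from the motor neuron groups alone, and the single non-motor-neuron arrays were assumed to vary alike. Motor neurons and non-motor neurons were compared in an additive model of genotype label and cell type, with 3 residual degrees of freedom. Genotype labels in non-motor neurons, with no replicates, were compared as values. With 2 arrays against 2, an exact permutation test of a single gene cannot give a p below 0.333, so the calls rest on the spread shared across genes. Where all arrays of a group were below background, the fold was computed against a floor, the lowest signal called well above background. The probe's own signal was used where it exceeded this floor. The fold is given as a lower bound on the ratio of group means and leaves out their spread. Genes were ranked by their fitted difference, which for these genes also rests on signals below that floor.

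Gene lists were fixed before the data were examined: reported cluster targets, motor neuron identity, lateral and other motor columns, Hox genes, progenitors, proliferation, interneurons, sensory neurons and neural crest, endothelium, erythroid cells, microglia, mesenchyme, floor plate, p53 response, apoptosis, PI3 kinase pathway, NEDD4-family ligases, axon guidance, immediate early genes and sex-linked genes. They were tested with camera (preset correlation of 0.01, and an estimated correlation beside it) and fry, adjusted over the 20 lists with enough measured genes. In non-motor neurons, each list's median was ranked among 10000 random lists matched on mean expression. Some genes stand in more than 1 list, such as Fabp7 and Lhx3.

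Named genes followed a rule fixed before the data were examined. Per tested comparison these were the 10 higher and 10 lower genes with the largest change among those past the threshold without overlap between groups. Up to 4 members per list with the largest change were added, together with Mir17hg, Bcl2l11, Ndfip1, Cdkn1a, E2f1, Mnx1, Isl1, Chat, Foxp1, Lhx3 and Xist. Fcer1g, Cx3cr1, Cyld, Nefl, Hba-a1, Slc4a1, Pax2 as an example of probes with the same sign, Oc90, Hoxc13 and Tfap2d were chosen after their values were seen. So were the comparison of probes of the same gene and the summary by kind of probe. Some genes that the rule takes are not reported here.

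The steps were tested on simulated data of the same size and spread, with 14917 genes. Few of these genes were changed, and recovery depends on how many change, so the shares below set no limit for the real arrays. For the genotype comparison in motor neurons, 0 of 66 genes changed by 1 log2, 1 of 67 changed by 2 and 59 of 67 changed by 4 were recovered, with 5 unchanged genes called. For the comparison of motor neurons with non-motor neurons, 0 of 66, 2 of 67 and 61 of 67 were recovered, with 0 unchanged genes called by limma. For the interaction, none was recovered at any of these sizes.

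Alternatives fixed before the data were examined covered normexp background correction with an offset of 50, quantile and median scaling, the authors' value table, the filter on dim probes, the choice of probe per gene, a trended robust prior, replicate and tag blocks, other models, an estimated correlation in camera, and leaving out each array. Normexp used the raw median spot signal with the local background median, in place of the mean spot signal. Added after the data were seen were a 75th percentile over detected probes, the spike-in signal as a covariate, fits within one genotype label, and a crossed replicate block. A planned test of microRNA seed sites in 3' UTRs was not run, because no transcript sequences were used here.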

Results

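Transcript levels were measured on 1-colour microarrays in cells sorted from the spinal cord of E12.5 mouse embryos. The embryos carried a Hb9::GFP reporter, which marks spinal motor neurons, and were labelled as homozygous knockouts of the microRNA cluster mir-17~92 or as wild type. GFP-on cells (motor neurons) were hybridised to 2 arrays per genotype label, and GFP-off cells (non-motor neurons) to 1 array per genotype label, 6 arrays in all. The 75th percentile of the processed signal was 67.0 and 579 on the knockout-labelled motor neuron arrays (replicates 1 and 2), and 51.0 and 65.8 on the wild-type-labelled ones. It was 628 and 378 on the knockout-labelled and wild-type-labelled non-motor-neuron arrays. In the same order, 44.0%, 60.0%, 41.0%, 43.9%, 62.3% and 58.9% of the probe spots were well above background. After filtering, 14917 genes were tested, and the number of arrays limits the precision of every value below.

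The targeted locus was examined first. Mir17hg, the host gene whose transcript carries the mir-17~92 hairpins, was seen by 1 probe. Relative to each array's 75th percentile, its log2 signal was 4.55 and 4.78 on the knockout-labelled motor neuron arrays and 4.62 on the knockout-labelled non-motor-neuron array. It was -2.38 (not above background) and 2.73 on the wild-type-labelled motor neuron arrays and -1.23 on the wild-type-labelled non-motor-neuron array. All 3 knockout-labelled arrays thus lay above all 3 wild-type-labelled arrays, by a log2 difference of 4.49 ± 1.31 (SE, n = 2 against 2, adjusted p = 0.0402, limma) in motor neurons and 5.85 in the unreplicated non-motor-neuron pair. This direction goes against the labels if the probe lies in the deleted part; a probe outside that part checks nothing, and its position relative to the deletion was not known. The genotypes are therefore named below as labelled, and the direction of each genotype difference rests on those labels.

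**Figure D1:**
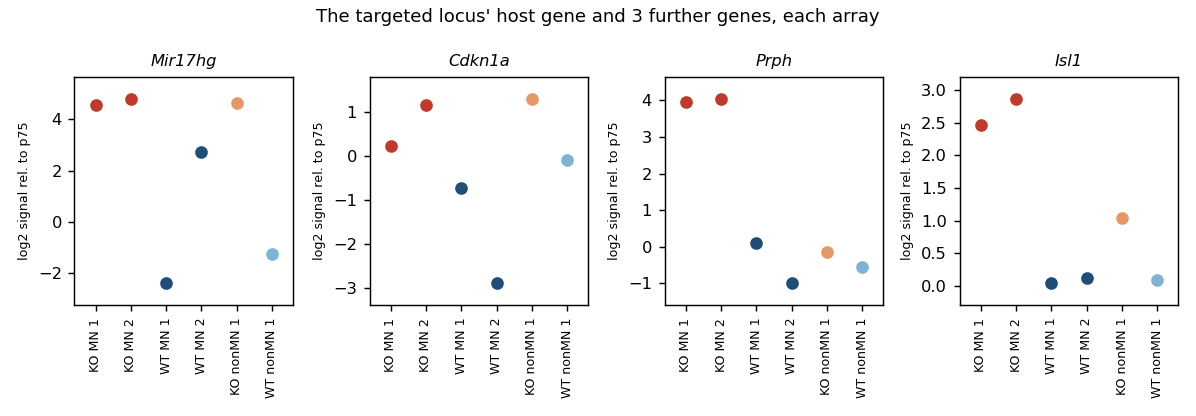
Log2 signal relative to the array's 75th percentile (y axis) on each of the 6 arrays (x axis; KO and WT, knockout-labelled and wild-type-labelled; MN, motor neurons) for Mir17hg, Cdkn1a, Prph and Isl1; each point is 1 array. Mir17hg was higher on all 3 knockout-labelled arrays (lowest 4.55) than on any wild-type-labelled array (highest 2.73).

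The comparison of genotype labels within motor neurons asks which transcripts change when the cluster is lost, including its reported targets. The knockout-labelled motor neuron arrays lay in slide row 1 and the wild-type-labelled ones in row 2, so label and row cannot be told apart here. Of the 28 measured genes reported as targets, 10 rose in the knockout-labelled arrays, 1 fell and 17 did not pass the test (12 rose and 2 fell when adjusted over the list alone). Cdkn1a, the cell cycle inhibitor p21, rose by 2.50 ± 0.73 on the log2 scale (SE, n = 2 against 2, adjusted p = 0.0397), the secreted matrix protein gene Thbs1 by 3.73 ± 0.73, and the hypoxia regulator Hif1a by 3.21 ± 0.51. The ubiquitin ligase gene Mylip rose by 4.36 on one probe and gave -0.41 on the other, and Rbl1, a retinoblastoma family member, was at least 5.72-fold higher on one probe and gave a log2 difference of 0.02 on the other. The deubiquitinase gene Cyld was the target that fell (-2.27). The log2 differences of the pro-apoptotic gene Bcl2l11 (0.05), of E2f1 (-0.33) and of the ubiquitin ligase adaptor Ndfip1 (-0.18) did not pass. For Cdkn1a, Thbs1 and Mylip, 1 of the 2 wild-type-labelled arrays was below background, so the size is approximate. With the spike-in signal as a covariate, which itself parted the labels of the motor neuron arrays, Cdkn1a gave -0.60 ± 1.65. The target list as a whole was not called by camera (p = 0.0254, adjusted p = 0.169; adjusted p = 0.992 with an estimated correlation); fry gave p = 0.0334 towards higher values.

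Among 15 motor neuron identity genes, 4 rose in the knockout-labelled arrays and 11 did not pass (4 rose when adjusted over the list alone). Prph, encoding the intermediate filament peripherin, rose by 4.44 ± 0.53 (adjusted p = 0.00542), and the LIM homeodomain genes Isl1 and Isl2 rose by 2.57 ± 0.47 and 1.97 ± 0.58 (Isl2 gave -0.021 ± 1.65 with the spike-in covariate). The choline transporter gene Slc5a7 was at least 2.32-fold higher on its brighter probe, with a log2 difference of 0.51 on the other. On the wild-type-labelled motor neuron arrays, Prph (0.11 and -0.99) and Isl1 (0.05 and 0.12) had log2 signals not clearly above those of GFP-off cells. The knockout-labelled and wild-type-labelled non-motor-neuron arrays gave -0.13 and -0.55 for Prph, and 1.04 and 0.09 for Isl1. The brighter Slc5a7 probe was below background on both wild-type-labelled motor neuron arrays. Chat, Lhx3, Lhx4 and Slc18a3 were higher there than on both non-motor-neuron arrays. Chat, which makes acetylcholine (-0.34), and Lhx3 (0.37) did not pass, nor did Foxp1 of limb-innervating motor neurons, whose 3 probes gave -0.77, 1.42 and -2.16. Of the 10 measured genes of microglia and macrophages, 6 also rose: the mannose receptor gene Mrc1 (at least 9.35-fold), the adaptor Tyrobp (at least 12.2-fold), the complement gene C1qa (at least 2.74-fold), C1qc (2.85 ± 0.51 log2), the chemokine receptor gene Cx3cr1 on both probes (2.58 and 2.08 log2), and Fcer1g (1.68 log2). Camera did not call that list after adjustment (p = 0.00456, adjusted p = 0.0912; adjusted p = 0.992 with an estimated correlation).

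Over all genes, 2354 were higher and 1080 lower in the knockout-labelled motor neuron arrays. The 10 with the largest increase included Pbk, a mitotic kinase (at least 11.4-fold), the nuclear pore gene Seh1l (at least 12.0-fold; 0.01 log2 on its other probe), the angiotensin receptor gene Agtr2 (at least 11.5-fold), Rcn2 (at least 15.8-fold), Mrc1, the vesicle GTPase gene Rab31 (at least 7.98-fold), the actin-capping gene Tmod3 (at least 9.21-fold), Kctd5 (at least 8.30-fold) and the MAP kinase kinase gene Map2k1 (at least 8.93-fold). The 10 with the largest decrease included genes known from tissues other than the spinal cord. Cfap44, of motile cilia and sperm tails, was at least 43.7-fold lower, the sperm protein gene Smcp at least 22.3-fold, the placental protease gene Cts7 at least 14.0-fold, Papln at least 11.9-fold, the MHC gene H2-M11 at least 11-fold, the vomeronasal receptor gene Vmn1r197 at least 7.55-fold, the oocyte gene Btg4 at least 7.09-fold and the desmoglein gene Dsg1c at least 6.56-fold. Tnfrsf14 fell by 5.12 and Ms4a5 fell by 5.07 on the log2 scale, each with 1 of the 2 knockout-labelled arrays below background, so the size is approximate. Of 1442 probes for olfactory and vomeronasal receptors, 116 (8.04%) passed the filter on background, against 78.4% of the probes of other named genes. Their median log2 difference was -1.60, which depends in part on the filter, since a dim probe enters through the arrays on which it is high. In 911 of the 2354 higher genes, both wild-type-labelled motor neuron arrays were below background.

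Members of the remaining lists passed in both directions. Members that rose included the axon guidance receptor gene Nrp1 (at least 5.68-fold), the immediate early gene Fos (at least 9.15-fold), the heat shock gene Hspa1a (at least 4.70-fold), Fabp7 of radial glia (2.98 log2), and the cell cycle genes Ccnd1 (3.11 log2) and Top2a (2.55 log2). The guidance receptor genes Dcc and Plxna1 fell by 2.11 and 2.36. Hoxa5 and Hoxb5 rose by 1.81 and 1.82, Zeb2 rose by 1.59 (0.32 on its other probe), and Runx1 fell by 1.78 (1 knockout-labelled array below background; 1.31 on its other probe). Rises and falls numbered 3 and 0 of 19 for proliferation (limma), 3 and 2 of 22 for progenitors, 4 and 2 of 20 for interneurons, 3 and 1 of 10 for sensory neurons and neural crest, 2 and 3 of 26 for axon guidance, 3 and 0 of 12 for immediate early genes, 5 and 0 of 21 for the PI3 kinase pathway, 3 and 0 of 14 for the p53 response, and 3 and 0 of 15 for apoptosis. They numbered 2 and 0 of 12 for mesenchyme, 2 and 1 of 10 for endothelium, 2 and 0 of 9 for erythroid cells, 2 and 0 of 23 for Hox genes, 0 and 1 of 15 for the lateral motor column, 1 and 0 of 9 for the other motor columns, and 1 and 1 of 11 for NEDD4-family ligases, while none of 5 floor plate genes passed. When adjusted over the list alone, the counts differed for proliferation (2 and 0), progenitors (6 and 2), immediate early genes (4 and 0), the PI3 kinase pathway (5 and 1), endothelium (2 and 2) and NEDD4-family ligases (4 and 2), and were 0 and 0 for the Hox and both motor column lists. Camera called 0 of 20 lists, with 4 at an unadjusted p under 0.05. It placed the lateral column, other column, interneuron, endothelium and NEDD4 lists below the other genes although their medians were above 0, and the erythroid list had a median of -0.15 and a mean of 0.21. Xist, the only sex-linked gene tested, gave 0.64 and did not pass. The files name 5 further probes XIST; these, not matched by accession and not tested, gave -0.92 to -1.73.

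The genotype difference was compared between probes of the same gene. Across 3887 genes with 2 probes above background, the log2 differences of the brighter and the second probe correlated with r = 0.0403 (across genes, which are not independent replicates). Of 777 called genes with more than 1 probe, 359 (46.2%) had the same sign on all probes, Papln, Cx3cr1 and Pax2 among them. Where the brighter probe differed over 2-fold, the second had the same sign in 50.9% of genes, against 50.2% with shuffled partners. Agreement of sign in a single gene can therefore arise by chance. When probes were tested singly, every probe was called higher for 79 genes and lower for 40, and 136 genes had probes called in both directions. For the difference between motor neurons and non-motor neurons, the same correlation was 0.496 over all arrays, 0.665 within the knockout-labelled and 0.266 within the wild-type-labelled arrays. For the genotype difference in non-motor neurons it was 0.217. Between the 2 wild-type-labelled motor neuron arrays it was 0.0606, and between the 2 knockout-labelled ones 0.206.

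**Figure D2:**
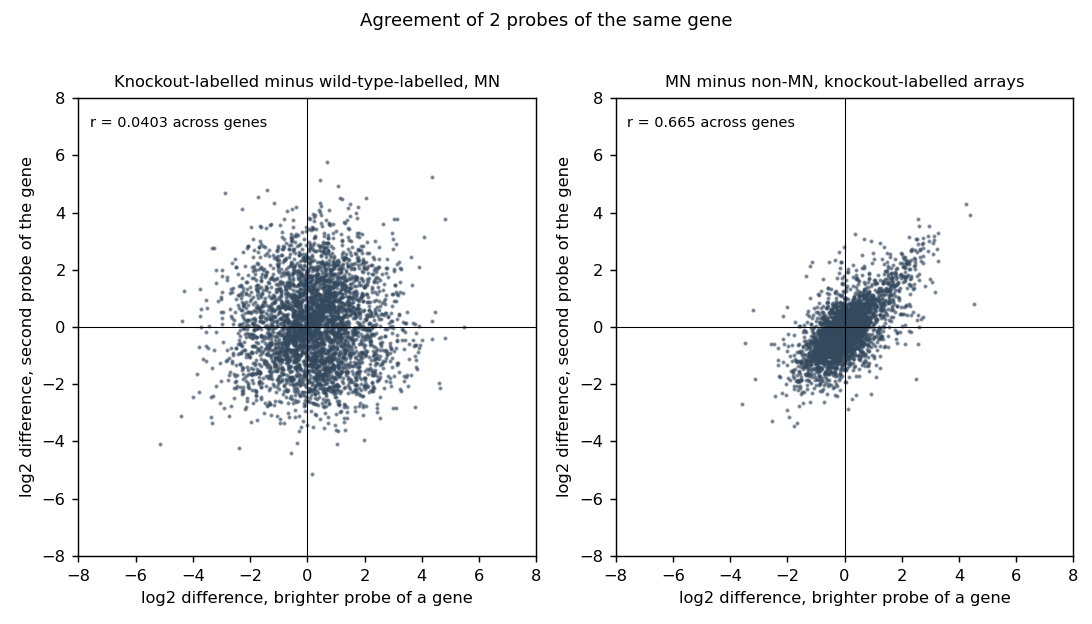
Log2 difference on the brighter probe (x axis) and the second probe (y axis) of the same gene, for knockout-labelled minus wild-type-labelled motor neurons (left) and for motor neurons minus non-motor neurons in the knockout-labelled arrays (right); each point is 1 of 3887 genes. The correlation across genes was 0.0403 on the left and 0.665 on the right.

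The counts of 2354 and 1080 came from limma, with 5726 genes at an unadjusted p under 0.05, a median log2 difference over all genes of 0.34, and 67.3% of genes without overlap between the groups (33.3% by chance). They fell to 0 and 0 in an additive model over all 6 arrays (4662 at an unadjusted p under 0.05) and with no filter on dim probes (5043), to 1 and 7 with the spike-in signal as a covariate, to 656 and 249 without knockout-labelled replicate 2 and to 1434 and 651 without knockout-labelled replicate 1, and rose to 4820 and 2192 without wild-type-labelled replicate 1. The additive model fits 1 genotype difference for both fractions, so it does not test motor neurons alone. The share of called genes that were higher went from 68.5% to 89.7% when each array's median was subtracted (median over all genes 0.98), to 88.9% with quantile normalization and to 79.4% with normexp background correction. Correlations between arrays covered the 10135 genes above background on all 6. Wild-type-labelled motor neuron replicate 2 gave 0.71 to 0.798 with all arrays but replicate 1 (0.926). Replicate 1 gave 0.825 to 0.8945 with the remaining arrays, which gave 0.9085 to 0.980 among themselves. The wild-type-labelled motor neuron arrays thus stood apart, and why was not tested.

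The comparison of GFP-on with GFP-off cells asks what distinguishes motor neurons from the rest of the sorted cord. Motor neuron identity genes were higher in the GFP-on arrays: 5 of 15 measured members rose, and 10 when adjusted over the list alone. The LIM homeodomain gene Lhx4 rose by 3.88 ± 0.41 on the log2 scale (SE, n = 4 against 2, adjusted p = 0.00940), the vesicular acetylcholine transporter gene Slc18a3 by 3.48 ± 0.43, Chat by 3.17 ± 0.43, Lhx3 by 2.78 ± 0.49 and the neurofilament gene Nefl by 2.50 ± 0.42. Genes of red blood cells were lower: 6 of 9 fell, and 7 when adjusted over the list alone. Among them the globin genes Hbb-b2, Hba-x and Hbb-bh1 fell by 4.50, 3.18 and 3.14, and Alas2, the first enzyme of haem synthesis in red cells, by 3.08; Hba-a1 and the anion exchanger gene Slc4a1 gave -2.90 and -2.59. Camera called both lists (adjusted p = 9.04e-09 and 2.01e-07; adjusted p = 0.332 and 0.431 with an estimated correlation).

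**Figure D3:**
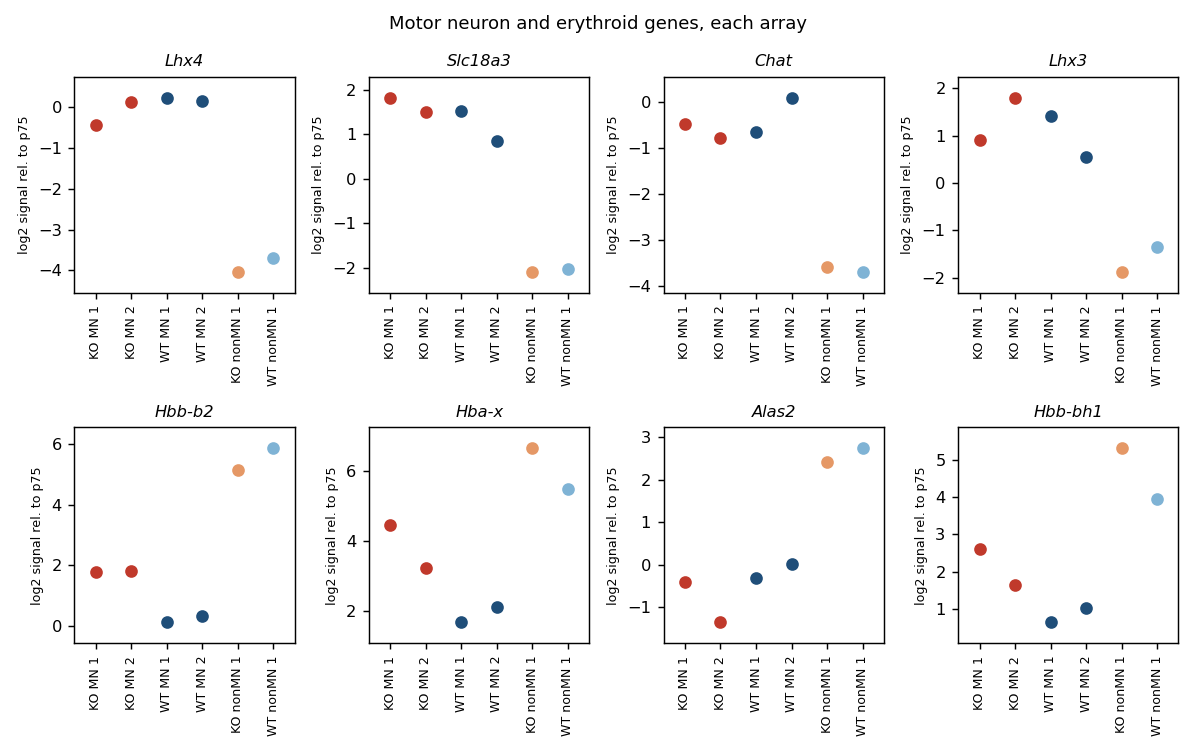
Log2 signal relative to the array's 75th percentile (y axis) on each of the 6 arrays (x axis; KO and WT, knockout-labelled and wild-type-labelled; MN, motor neurons) for 4 motor neuron genes (top) and 4 erythroid genes (bottom); each point is 1 array. Lhx4, Slc18a3, Chat and Lhx3 were higher on all 4 motor neuron arrays than on both others, and the erythroid genes were lower.

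Other neural genes were also higher in the GFP-on arrays. In the lateral motor column, interneuron and sensory and neural crest lists, 2 members each rose, of 15, 20 and 10 measured (4, 5 and 5 when adjusted over the list alone). They were Cpne4 (2.47) and Pou3f1 (2.43), the interneuron transcription factor genes Evx1 (3.84) and Pax8 (2.67), and the neural crest transcription factor genes Foxd3 (4.29) and Sox10 (3.93). Camera called the 3 lists (adjusted p = 0.0480, 2.60e-06 and 8.40e-05; adjusted p = 0.458, 0.332 and 0.431 with an estimated correlation). Hoxc11, of the caudal cord, rose by 2.57, 1 of 23 Hox genes to pass, and the axon growth gene Chl1 by 2.63 (2.32 on its other probe), 1 of 26 guidance genes. Isl1 (0.81) and Foxp1 (-0.06) did not pass.

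The mesenchyme, proliferation and immediate early lists had members with lower values in the GFP-on arrays. Mesenchyme genes included Fn1 (-1.88), Lum (-1.66) and Dcn (-1.29). None of 12 mesenchyme genes and none of 19 proliferation genes passed over all genes, and 5 mesenchyme genes fell when adjusted over the list alone. The cell cycle gene Top2a gave -1.98, and the immediate early genes Fos and Egr1 gave -3.13 and -2.65, none of them past the test; 4 immediate early genes fell when adjusted over the list alone. Camera called the mesenchyme, proliferation and immediate early lists lower (adjusted p = 0.00634, 0.00850 and 0.0327; adjusted p = 0.693, 0.724 and 0.693 with an estimated correlation). It did not call the reported cluster targets (adjusted p = 0.0819), Hox (0.0963), progenitor (0.129), axon guidance (0.254), p53 (0.313), other motor column (0.634), apoptosis (0.697), PI3 kinase (0.816), microglia (0.816), NEDD4 (0.827), endothelium (0.994) or floor plate (0.994) lists. Of these lists, the other motor columns had 2 members past the test, Lhx3 and Lhx4; when adjusted over the list alone, 2 cluster targets, 3 progenitor genes and 1 p53 gene fell and 2 progenitor genes rose. The other column, Hox and guidance lists had medians below 0 (-0.26, -0.03 and -0.12) with means above 0, and camera placed the PI3 kinase and NEDD4 lists above the other genes with medians of -0.07 and -0.16.

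Over all genes, 230 were higher and 112 lower in motor neurons. The 10 largest increases were in the synaptotagmin gene Syt10 (6.99 ± 1.11 log2), the sperm nuclear protein gene Prm1 (at least 30.0-fold), the homeodomain gene Dmbx1 (5.12), the ghrelin receptor gene Ghsr (at least 7.77-fold), Onecut3 (at least 6.73-fold), the matrix glycoprotein gene Tnr (at least 7.32-fold), the nuclear receptor genes Nr5a2 (4.35), Esrrg (4.31, and 4.17 on its other probe) and Esrrb (4.23), and Foxd3. Syt10 and Prm1 also differed between genotype labels in motor neurons, by -3.91 and -4.13 (for Prm1, with 1 knockout-labelled array below background). The largest decreases were in Hbb-bs (fell by 5.41 ± 0.62) and Hbb-b2, the neutrophil genes Stfa2l1 (-3.76) and Ltf (-3.69), the cartilage and matrix genes Epyc (-3.52), Matn1 (-3.28) and Aspn (-3.23), and Inhba (-3.39), Pdzk1ip1 (-3.30) and Fitm1 (-3.21). Their sizes are approximate where motor neuron arrays were below background. Only 1 of 4 was above it for Ltf, Stfa2l1, Epyc and Fitm1, 2 of 4 for Aspn and Inhba, and 3 of 4 for Matn1 and Hbb-bs. For Dmbx1, 1 of the 2 non-motor-neuron arrays was above it. Of 68 called genes with more than 1 probe, 67 had the same sign on all probes.

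Limma gave 3291 genes at an unadjusted p under 0.05 here, with a median log2 difference over all genes of -0.21 and 27.7% of genes without overlap (13.3% by chance). The counts of 230 and 112 fell to 0 and 0 with quantile normalization (2917 at an unadjusted p under 0.05), with no filter on dim probes (5667), without wild-type-labelled motor neuron replicate 1 (2659) and without the wild-type-labelled non-motor-neuron array (1416), and to 22 and 4 without knockout-labelled motor neuron replicate 1. They rose to 532 and 570 without knockout-labelled motor neuron replicate 2 and were 223 and 650 without the knockout-labelled non-motor-neuron array. The share of called genes that were higher was 67.3%, against 53.7% with each array's median subtracted (median over all genes -0.35) and 52.8% with normexp. Within the knockout-labelled arrays alone, 659 and 286 genes were called (228 and 101 shared with the counts above). Within the wild-type-labelled arrays alone, the counts were 335 and 768 (100 and 65 shared; 30.4% higher). With the tag that the sample descriptions share between GFP-on and GFP-off arrays as a block, 556 and 472 genes were called (fixed, 54.1% higher) or 752 and 717 (random, 51.2% higher).

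Whether the genotype difference itself differed between motor neurons and non-motor neurons was tested as an interaction. Limma called 0 genes, with 1431 at an unadjusted p under 0.05 and a smallest adjusted p of 0.209, for the sperm gene Smcp. No size is given for it, because both knockout-labelled motor neuron arrays and the wild-type-labelled non-motor-neuron array were below background. In simulated data of this size with few changed genes, none of 67 genes with a log2 interaction of 4 was recovered. The absence of calls therefore does not exclude differences of that size. Recovery depends on how many genes change, so the simulation sets no limit for the real arrays. The count became 79 with each array's median subtracted, and 1472, 306, 22 and 12 without wild-type-labelled replicate 1, wild-type-labelled replicate 2, knockout-labelled replicate 1 and knockout-labelled replicate 2, each of which leaves 1 residual degree of freedom.

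In non-motor neurons, 1 knockout-labelled array was set against 1 wild-type-labelled array with no test. Genes of microglia and macrophages were higher in the knockout-labelled array: all 10 measured members lay above 0, with a median log2 difference of 1.32 (percentile 100 among 10000 random lists matched on mean expression). Mrc1 gave 2.70, C1qa 2.45, C1qc 1.58, and the 2 probes of Cx3cr1 1.31 and 1.60. Proliferation genes were higher in 18 of 19 cases (median 0.59, percentile 100), mesenchyme genes in 10 of 12 (0.44, percentile 100), and reported cluster targets in 22 of 28 (0.37, percentile 99.8), while Hox genes were lower in 17 of 23 (-0.43, percentile 0) and endothelial genes in 9 of 10 (-0.80, percentile 0.01). Interneuron (-0.19, percentile 1.99) and progenitor genes (-0.13, percentile 3.39) also lay low, and the other lists fell between percentiles 13.3 and 91.0. A percentile ranks genes within 1 pair of arrays, so it gives no measure of variation between preparations of the same label.

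More than a 2-fold difference was seen for 480 genes higher and 495 lower in the knockout-labelled non-motor-neuron array. Genes chosen for their size after the values were seen were Taf7 (-7.47) and, at rank 5 by absolute size, Mir17hg (5.85), and Oc90, Hoxc13 and Tfap2d, which were below background on 1 of the 2 arrays and are given no size. Of the genes called in motor neurons, 87.4% had the same sign in non-motor neurons, against 75.2% of all genes, with a median absolute log2 difference of 2.29 in motor neurons and 0.40 in non-motor neurons. Across genes, the genotype differences of the 2 fractions correlated with r = 0.48 and rho = 0.58. The counts became 132 and 225 with normexp, 1026 and 281 with each array's median subtracted, 734 and 1009 with no filter on dim probes, and 84 and 218 among probes above background on all 6 arrays.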

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

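All tests in this part were chosen after the results they measure had been seen. Probes that matched no gene were left out of the comparisons, yet 13662 of them were well above background on at least 2 of the 6 arrays; their median log2 difference between genotype labels in motor neurons was -0.99, and 74.1% were lower in the knockout-labelled arrays, among probes that this filter in part selects.

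The first pattern is the large genotype difference in motor neurons, with 2354 genes higher and 1080 lower. A change of transcript level in most called genes is argued against by the probes. Across 3887 genes, the difference on the brighter probe correlated with that on the second at r = 0.0403. The upper 95% limit of 0.0716 treats genes as independent, which they are not. Among 2037 genes with probes above background on all 6 arrays, r was 0.0982, against 0.604 for the cell type difference. Of the variance of the genotype difference across genes, 81.9% was beyond what the spread between replicates gives. The correlation between probes for the cell type difference reached 0.496 over the 3887 genes (0.665 in the knockout-labelled and 0.266 in the wild-type-labelled arrays). Array brightness alone is argued against as well, since the 2 knockout-labelled arrays differed in brightness by 3.08 log2 and the genotype groups by 1.64, while the spread across genes between those arrays was 0.488 of the genotype difference; the 2 wild-type-labelled arrays, 0.412 apart in brightness, gave 0.697, also little shared between probes (r = 0.0606), so such differences arose within a label too. A signal bound to single probes is a candidate explanation: between the fractions, the genotype difference of the same probe correlated at r = 0.624 (0.580 for the second probes), and that of one probe with its partner at 0.0186 and 0.0192. What binds it to the probe stays open, as do single genes. The spike-in signal relative to the 75th percentile also parted the groups (6.11 and 5.20 against 7.16 and 7.66). With it as a covariate, 1 gene was higher and 7 lower, and Isl2 went from 1.97 ± 0.58 to -0.021 ± 1.65. Because the covariate parts the labels of the motor neuron arrays, this fit can hardly separate label from spike-in signal, and the error grows. The fall in calls therefore decides nothing about the cause. Slide row also coincided with the label in motor neurons and cannot be told apart from it there.

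The second pattern is Mir17hg, which was higher on the knockout-labelled arrays. A probe-bound signal, the candidate of the first pattern, stays open: in non-motor neurons Mir17hg lay 9.66 residual standard deviations above the value that other genes with its motor neuron difference had, at rank 7 of all genes, but this is a single pair of arrays. An exchange of the genotype labels of all arrays stays open. The lowest knockout-labelled array lay 1.81 log2 above the highest wild-type-labelled one. Reported targets ran as the labels say (10 rose and 1 fell in motor neurons, 22 of 28 were higher in non-motor neurons). Camera did not call the list in motor neurons (adjusted p = 0.169, and 0.992 with an estimated correlation). Of all called genes in motor neurons, 68.5% were higher as well. The genotype difference was also little shared between probes of a gene, so the targets do not settle the labels. A host transcript that stays high when the hairpins are deleted, seen by a probe outside the deleted part, stays open too and is the biological alternative; it predicts a difference in both fractions, and non-motor neurons gave 5.85. These cannot be told apart while the position of the probe relative to the deletion is unknown, so every genotype direction in the report could be turned.

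The third pattern is the higher level of interneuron and neural crest genes in the GFP-on fraction, a sort meant to leave those cells out. Fewer blood and mesenchymal cells would raise neural genes alike, and this stays open: crest genes (9 members, median 1.45) exceeded progenitor genes (21 members, 0.39; exact permutation test, 2-sided p = 0.0411, Fabp7 of both lists left out), but the sort itself may remove progenitors, the proliferation list being lower (median -0.76), and interneuron genes were not compared. Cells of these types inside the gate may contribute: 21 of 30 members were higher under both genotype labels, among them Sox10 and Foxd3, but not all. Transcription by the motor neurons themselves is the biological alternative, with a median of 1.03 over the members, and it cannot be told apart from such cells in sorted pools. Several members, such as Slc17a6 and Gad1, also differed between genotype labels on their single probes.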

How the results depend on the processing

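The 75th percentile over detected probes, the spike-in covariate, the fits within one genotype label and the crossed replicate block were chosen after the data were seen. The cause of each change below was not tested. For the genotype labels, the additive model fits 1 difference for motor neurons and non-motor neurons together, so it does not test motor neurons alone. The spike-in signal parted the labels of the motor neuron arrays, so the fit with that covariate can hardly separate label from spike-in signal. For knockout-labelled against wild-type-labelled motor neurons (2354 genes higher, 1080 lower), the counts were 1123 and 291 with normexp, 1513 and 189 with quantile normalization, 4634 and 531 with each array's median subtracted, 0 and 0 with no filter (5043 at an unadjusted p under 0.05 in limma), 1533 higher among probes above background on all 6 arrays, 630 lower with the 75th percentile over detected probes, 0 and 0 in the additive model (4662), and 1 and 7 with the spike-in covariate. Leaving out 1 array gave 656 to 4820 higher and 249 to 2192 lower. The authors' value table gave 2360 and 1079.

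For motor neurons against non-motor neurons (230 higher, 112 lower), the counts were 229 lower with normexp, 0 and 0 with quantile normalization (2917 at an unadjusted p under 0.05 in limma), 0 and 0 with no filter (5667), 416 higher among probes above background on all 6 arrays, 466 and 542 from 4 group means, 659 and 286 in knockout-labelled arrays only, and 768 lower in wild-type-labelled arrays only. Leaving out 1 array gave 0 to 532 higher and 0 to 650 lower. The interaction (0 genes) gave 1 with normexp, 79 with each array's median subtracted, and 12 to 1472 when 1 motor neuron array was left out. For non-motor neurons (480 and 495), the counts were 132 and 225 with normexp, 1026 and 281 with each array's median subtracted, 734 and 1009 with no filter, and 84 and 218 among probes above background on all 6 arrays.

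With the replicate number as a block, the motor neuron genotype counts were 2435 and 1172, and crossing the numbers gave 3479 and 1788; deviations of same-numbered arrays correlated at -0.152 over 2 pairs. The replicate block gave 34 genes for the interaction, and 2 lists higher between genotype labels and 2 lists lower between cell types. For cell types, the shared tag as a fixed block gave 556 and 472, and as a random block 752 and 717.

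Lists called higher between genotype labels (0) became 3 with normexp, 2 with each array's median subtracted, 5 with no filter, and 0 to 3 when 1 array was left out. Between cell types, camera at the preset correlation called 4 lists higher and 4 lower, with 10 lists at an unadjusted p under 0.05. The calls became 0 and 0 with an estimated correlation in camera, and 2 to 6 higher and 2 to 5 lower when 1 array was left out. Signs turned for genes that had not passed: between genotype labels, Ndfip1 gave 0.25 with normexp, 0.46 with the median and 0.61 with the spike-in covariate, Bcl2l11 -0.69 with normexp, -0.12 with detected probes, -0.039 in the additive model and -0.059 with the covariate, E2f1 0.0053 with normexp and 0.31 with the median, Chat 0.30 with the median and 0.73 with the covariate, and Lhx3 -1.63 and Xist -0.45 with the covariate. Of the called genes named in the text, Cdkn1a (-0.60) and Isl2 (-0.021) turned with the covariate. Of all 3434 called genes, the sign turned for 229 with the covariate, 256 with normexp, 65 with the mean of a gene's probes, 1 with quantile normalization and 1 with no filter. When probes were tested singly it turned for 54, all called the opposite way. Among probes above background on all 6 arrays it turned for 30 of 1771, with 9 called the opposite way. Of the 342 genes called between cell types, 11 turned with normexp. Between cell types, Foxp1 gave 0.0065 with detected probes and 0.48 in wild-type-labelled arrays only, and Isl1 -0.0066 there. Leaving out 1 array gave Ndfip1 -0.53 to 0.18, Bcl2l11 -0.65 to 0.75, Chat -0.71 to 0.032 and Lhx3 -0.076 to 0.81 between genotype labels, and Foxp1 -0.60 to 0.48 and Isl1 -0.0066 to 1.62 between cell types.

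Not run were all alternatives of the seed-site test, for which no sequences were used, the prior and replicates of the unreplicated pair, and the interaction without a non-motor-neuron array. Leaving 1 array in a group assumed that it varied like the others. Signal over background was lowest on wild-type-labelled motor neuron replicate 1, with 41.0% of spots well above it. By correlation across genes, wild-type-labelled motor neuron replicate 2 stood furthest from the other arrays.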

Other observations

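The genes and probes in this part were chosen after the data were seen. Most genes of microglia and macrophages had higher values on the knockout-labelled arrays, though camera did not call the list in motor neurons (adjusted p = 0.0912; adjusted p = 0.992 with an estimated correlation), where 6 of 10 passed the test, and the non-motor-neuron arrays were compared without a test. Of 13 probes for 10 measured genes, 11 had a log2 difference above 0 in motor neurons and 12 in non-motor neurons. Both probes of the chemokine receptor gene Cx3cr1 lay above 0 in motor neurons (2.58 and 2.08) and in non-motor neurons (1.31 and 1.60). Exceptions in motor neurons were the leukocyte gene Ptprc (-0.96) and 1 of the 3 probes of the growth factor receptor gene Csf1r (-1.22). Csf1r's other probes gave 0.27 and 0.53, and in non-motor neurons the probe that lay below 0 there gave -0.14, the only one of the 13 below 0.

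The interneuron genes Pax2 and Lmx1b went the other way, while the 2 probes of Barhl1 were split (-1.02 and 0.71 in motor neurons). All 3 probes of Pax2, a transcription factor gene of inhibitory interneurons, lay below 0 in motor neurons (-2.11, -2.49 and -2.18) and in non-motor neurons (-0.74, -1.07 and -1.82). Both probes of Lmx1b, of dorsal excitatory interneurons, lay below 0 in motor neurons (-2.16 and -2.79) and in non-motor neurons (-0.89 and -0.42).

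Probes for the Y-linked genes Ddx3y, Eif2s3y and Kdm5d were above background on none of the 6 arrays, 1 of the 2 probes for Uty was above background on 1 array, while all 6 probes named Xist or XIST were above background on all 6.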
